A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

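RNA was sequenced from meiotic cultures of WT, bas1 and ino4 yeast, 2 samples per genotype. Per the labels' protocols, cells were grown for 13.5 to 14 h at 30 °C in a presporulation medium with 1% yeast extract, 2% peptone and 1% potassium acetate and moved to 2% potassium acetate at 30 °C. For each sample 15 OD units were taken at 4 h in meiosis, per the labels. Total RNA was extracted with hot phenol and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name STAR, Cufflinks and the genome build sacCer2, without versions or settings. How the samples of a genotype were combined, whether strand was used in counting and how many reads were sequenced are not given in the sources used here.

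The deposited table holds FPKM values made by the authors (fragments per kilobase of gene model, scaled to the mapped fragments), 1 column per genotype per the file headers, for 6932 entries. Its entries carry identifiers of the form that the Cufflinks tools write, a gene symbol and a sacCer2 position, and 114 entries name several genes merged into a single model. A gene symbol is missing for 248 entries, 605 entries are listed at 0 in every genotype, and these include all 42 mitochondrial entries. An exact 0 can be a failed estimate, since 87 entries over the filter are listed at 0 in some genotype and 4 of these exceed an FPKM of 100 elsewhere. These 87 were left out of the comparisons. FPKM multiplied by length was checked for whole multiples of a read. At the best unit 13.1% of low values in WT, 15.4% in bas1 and 14.3% in ino4 came out whole within 0.05 reads. Chance gives 10% for a fixed unit, and picking the best of many units lifts that share. Reads could therefore not be recovered, the depth is unknown and no intervals or floors are given.

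Entries were compared when FPKM was at least 1 in at least 1 genotype and above 0 in all 3, which left 6153, of which 907 are listed at the same position as another entry and are said to overlap it. Values were taken as log2(FPKM + 1), with a pseudocount of 1 and no further scaling, and subtracted between genotypes. A difference of 1 on this scale was the rule for 2-fold. The planned limma test per sample and the planned camera test of gene lists need a value per sample. They were replaced by this description, as the plan provided for a table of group values, and no p-values are given. The planned filter of 2 samples became 1 genotype for the same reason, and the planned agreement between replicates could not be computed. The comparisons, the pseudocount, 22 gene lists and the rule for named genes were fixed before the data were examined. The 2-fold rule in place of a p-value was set afterwards.

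Named genes were BAS1, INO4, PHO2, GCN4, INO2 and OPI1, and, among genes at least 2-fold apart with an FPKM of at least 5 in a genotype compared, the 10 highest and 10 lowest against WT and the 5 highest and 5 lowest between the mutants. From each list the members at least 2-fold apart were named where there were 2 to 4, and otherwise the 4 largest differences were eligible. The planned form of this rule used p-values and values per sample, which were replaced by size. An item that the rule takes is not reported here. Genes outside the rule are said to have been named after their values were seen.

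For each list the median difference was given its percentile among 10000 random lists of equal size drawn to match on mean expression in 20 bins, as a description of these combined values. A list was said to stand apart outside the central 95% of those lists. Of 421 list genes, 407 were matched by symbol or synonym and the others are merged with a neighbour in the table. Gene synonyms came from the RefSeq annotation of assembly R64. Of 5411 symbols matched to it, 90.4% had the same length and 14.7% the same start, so its coordinates were not used with the table, and positions given are those of the table counted from 1. Of those lengths, 88.5% were multiples of 3, so most gene models have a coding length without UTRs.

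Before use, the steps were tested on simulated data for the 6153 genes, with 200 genes changed by log2 2. The 2-fold rule recovered 100% of them for bas1 against WT, 100% for ino4 against WT and 99.5% for bas1 against ino4, and it called 19, 48 and 46 unchanged genes. Noise was normal and sized to the median absolute difference between the genotypes, not to replicates. Changes of log2 2 lie well past the rule, so high recovery was built in. The calls of unchanged genes give no false-call rate for the real data. A simulated list of 20 genes shifted by log2 0.6 reached percentile 100 in all 3, and an unshifted list gave 73.59, 13.92 and 55.69. Alternatives tried were other pseudocounts, filters, 3 scalings (median, quantile and a trimmed mean of log ratios trimming 30% at each end), a 1.5-fold rule, entries of at least 300 bp and entries that overlap no other. Sequence shared between genes was counted as 30-base words in the R64 genome. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.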

Results

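Transcript levels were measured by RNA sequencing in meiotic cultures of budding yeast, Saccharomyces cerevisiae, at 4 h in meiosis. The 6 samples came from 3 genotypes, wild type (WT), a bas1 mutant and an ino4 mutant, with 2 samples per genotype. Bas1 is a Myb-related transcription factor that activates purine and histidine synthesis genes with its partner Pho2, and Ino4 is a basic helix-loop-helix factor that activates phospholipid synthesis genes as a dimer with Ino2. The authors' table gives 1 FPKM value per gene and genotype, so the spread between the samples of a genotype is unknown and no difference between genotypes has a replicate check. No test was made, and genes are called higher or lower from the authors' combined values alone. The number of reads behind a value is also unknown. Of 6932 entries in the table, 6153 were compared, with a median FPKM of 53.5 in WT, 53.6 in bas1 and 53.6 in ino4. Differences are given as log2(FPKM + 1), which understates the change of low genes, and folds are plain ratios of FPKM. A gene counts as at least 2-fold apart when the log2(FPKM + 1) difference is 1 or more in size. Across genes, which are not independent replicates, Pearson's r was 0.977 between bas1 and WT, 0.982 between ino4 and WT and 0.967 between the mutants.

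The targeted genes were each lowest in their own mutant. BAS1 (sacCer2 chromosome XI, 635489 to 637924) had an FPKM of 19.4 in WT, 21.1 in ino4 and 0.00985 in bas1. INO4 (chromosome XV, 111431 to 111886) had an FPKM of 307 in WT, 271 in bas1 and 0.339 in ino4. The genes on either side differed far less. UBP11 and SKG1 beside BAS1 had log2 differences of -0.24 and -0.18 in bas1, and ZEO1 and YOL107W beside INO4 had -0.19 and 0.05 in ino4. PCK1, beyond UBP11, had 0.64 in bas1. Among the other regulators, PHO2 had an FPKM of 112 in WT, 109.6 in bas1 and 109 in ino4. GCN4, the activator of amino acid synthesis genes, had 1843, 1759 and 1679. INO2 had 41.4 in WT, 22.6 in bas1 and 42.1 in ino4, and OPI1, the repressor of phospholipid synthesis genes, had 78.8, 56.9 and 75.9.

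The comparison of bas1 with WT asked which transcripts differ in meiotic cultures when Bas1 is missing. Genes of glycine and one-carbon metabolism and of purine synthesis were among the lowest in bas1. GCV1, which encodes the T subunit of the glycine decarboxylase complex (chromosome IV, 484161 to 485363), was 21.4-fold lower, with an FPKM of 365 in WT and 17.1 in bas1. SHM2, the cytosolic serine hydroxymethyltransferase (chromosome XII, 257993 to 259402), was 8.87-fold lower. ADE17, which encodes an enzyme of the last steps of inosine monophosphate synthesis (chromosome XIII, 507501 to 509279), was 5.18-fold lower, from 50.01 to 9.66. HPT1, which salvages hypoxanthine and guanine, was 3.78-fold lower. By contrast, genes of the middle phase of sporulation were mostly higher, led by the polo kinase gene CDC5 at 2.83-fold (144 in WT and 409 in bas1).

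In all, 60 genes were at least 2-fold higher in bas1 than in WT and 144 were at least 2-fold lower, or 33 and 91 with a pseudocount of 5. In the list for de novo purine synthesis, 3 of 11 genes were at least 2-fold lower and 8 lay between. These were ADE17, ADE12 (2.46-fold lower) and ADE4 (2.21-fold lower), which encodes the enzyme of the committed step. The list's median log2 difference was -0.56, below all 10000 random lists matched on expression (percentile 0), and 10 of the 11 members were lower in bas1. In the list for one-carbon and glycine metabolism, 3 of 7 genes were at least 2-fold lower, GCV1, SHM2 and GCV3 (2.38-fold), and the median was -0.40 (percentile 0.69). Its members went both ways, with 5 lower and 2 higher in bas1. The 5 histidine synthesis genes had a median of -0.22 (percentile 7.92). None was 2-fold lower, and the largest difference was at HIS4, with an FPKM of 18.6 in WT and 11.4 in bas1. The 5 guanine branch genes had a median of -0.07 (percentile 35.95), with HPT1 the only member 2-fold lower. Among 15 arginine and lysine genes the median was 0.11 (percentile 85.58), and LYS4, encoding homoaconitase, was 2.22-fold higher.

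Phosphate-responsive genes were also lower in bas1. Of 14 genes in this list, 5 were at least 2-fold lower, 9 lay between and 13 had a negative difference, with a median of -0.74 (percentile 0). SPL2, which restrains low-affinity phosphate uptake, was 4.72-fold lower, and the phosphate transporter genes PHO84 and PHO89 were 3.25-fold and 3.11-fold lower. VTC1, of the polyphosphate-making complex of the vacuole, was 2.74-fold lower. The fifth was the acid phosphatase gene PHO11, named after its values were seen, with an FPKM of 4.91 in WT and 1.80 in bas1. Of 11 mitotic and G1 genes, the cyclin gene CLN1 (2.33-fold) and the chitinase gene CTS1 (2.18-fold) were lower, and the median was -0.37 (percentile 0.18). CTS1 is listed at the same position as another entry.

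The list of middle sporulation genes had the highest median of the lists in bas1, 0.71, above all 10000 random lists (percentile 100). Of its 30 genes, 6 were at least 2-fold higher, 24 lay between and 29 had a positive difference. Besides CDC5, the list included SPO21 (2.28-fold), which builds the outer plaque of the meiotic spindle pole body, the kinase gene SPS1 (2.18-fold) and SSP1 (2.15-fold), which acts at the prospore membrane edge. NDT80, the transcription factor that turns on the middle genes, had an FPKM of 282 in WT and 525 in bas1. Genes used earlier in meiosis were nearer to WT in the values as reported. The median was 0.18 for 10 break formation genes (percentile 94), 0.17 for 15 axis and synapsis genes (percentile 95.30), 0.12 for 17 strand exchange and repair genes (percentile 90.11) and 0.17 for 10 meiotic entry regulators (percentile 94). Under quantile normalization the entry regulators had 0.34 (percentile 99.62), outside the central 95%. SPO11, whose product makes the meiotic DNA breaks, had an FPKM of 83.9 in WT and 104 in bas1. EXO1, a nuclease gene, had 39.8 and 78.1.

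**Figure D1:**
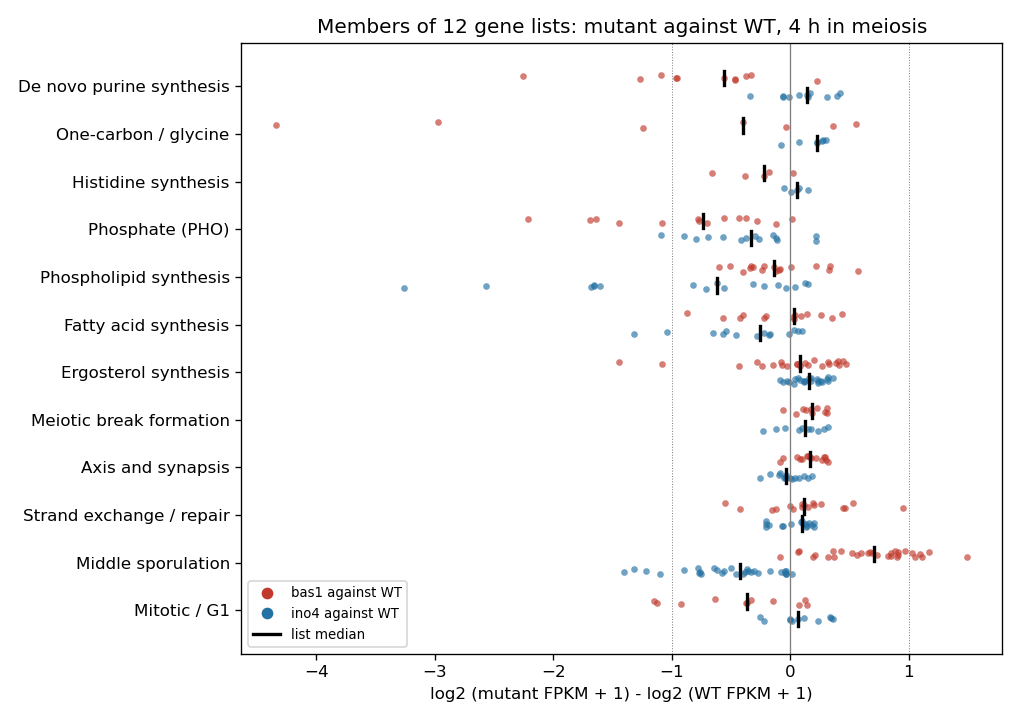
Members of 12 gene lists as the log2(FPKM + 1) difference of bas1 (red) or ino4 (blue) from WT on the horizontal axis. Each point is a gene, black bars are list medians and dotted lines mark 2-fold. Middle sporulation genes lie to the right in bas1 (median 0.71) and to the left in ino4 (median -0.43), and phospholipid synthesis genes lie to the left in ino4 (median -0.61).

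Of the remaining lists, 12 genes of the unfolded protein response had a median of 0.33 in bas1 (percentile 99.91), with ERO1 at 49.0 in WT and 73.6 in bas1, and no member 2-fold apart. The 129 ribosomal protein genes had a median of 0.11 (percentile 99.92), also with no member past the 2-fold rule, although RPL22A had a ratio of 2.04 (18.6 in WT and 37.8 in bas1). RPL22A is listed at the same position as BUD28, named after its values were seen, which had 8.51 in WT and 0 in bas1. Medians lay within the central 95% of random lists for phospholipid synthesis (-0.14), fatty acid synthesis (0.03), ergosterol synthesis (0.09), haploid mating genes (0.13), stress genes (-0.02), acetate use and gluconeogenesis (0.01) and marker loci (-0.19). Other settings took haploid mating genes to 0.22 (quantile normalization, percentile 98.64) or 0.19 (entries of at least 300 bp, percentile 99.21) and phospholipid synthesis to -0.18 (no shared positions, percentile 2.14), all outside the central 95%. Within the lists inside that range as reported, ERG3 and ERG20 of ergosterol synthesis were 2.74-fold and 2.15-fold lower, and the stress genes DDR2 and HSP12 were 3.49-fold and 2.30-fold lower. The DDR2 entry is only 186 bp long. Of the 21 lists with members that could be compared, 7 lay outside the central 95%, against 1.05 for lists of genes drawn at random. Genes of a list can differ together between cultures, so that figure is not a chance rate for these genotypes. The mitochondrial genome list had no member above 0.

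Outside the lists, the largest decreases in bas1 included 3 glycolytic genes. ENO1, encoding an enolase, was 5.45-fold lower, TDH3, encoding glyceraldehyde-3-phosphate dehydrogenase, was 5.25-fold lower, and GPM1, encoding phosphoglycerate mutase, was 4.56-fold lower. ENO1 and TDH3 share sequence with close paralogs and GPM1 is listed at the same position as another entry, so their values are less certain. SIP18, with a short entry of 240 bp, was 4.95-fold lower. Entries under 300 bp were 20.8% of those at least 2-fold lower in bas1, against 3.58% of those compared. YCR047W-A, at the same position as BUD23, had an FPKM of 7.08 in WT and 0.0124 in bas1. Among the largest increases, the cell wall mannoprotein gene TIR1 was 3.65-fold higher (102 in WT and 371 in bas1) and BSC1 was 2.89-fold higher. The small RNA gene SNR69 was 4.13-fold higher. The others were open reading frames that were short or listed at the position of another entry, YDR169C-A, YOR381W-A, YNL130C-A, YDL114W-A, BUD30 and YER148W-A, with log2 differences of 2.89, 2.01, 1.79, 2.09, 1.77 and 1.73. Strand use in the authors' counting is not given, so values of entries at a shared position may hold reads of either gene.

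**Figure D2:**
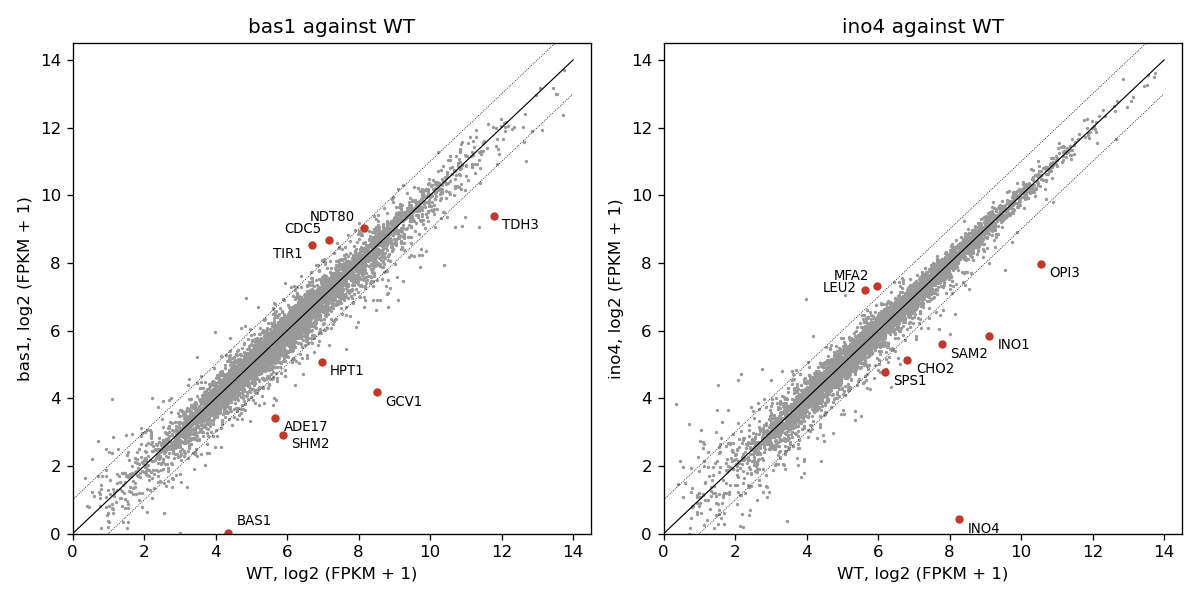
The authors' FPKM of each mutant (vertical axis) against WT (horizontal axis), both as log2(FPKM + 1), for the 6153 genes compared. The solid line marks equal values, dotted lines mark 2-fold and red points are named genes. GCV1 (log2 difference -4.34) lies far under the line in bas1, and INO1 (-3.26) and OPI3 (-2.56) lie far under it in ino4.

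The comparison of ino4 with WT asked which transcripts differ when Ino4 is missing. Genes of phospholipid synthesis were among the lowest in ino4. INO1, encoding inositol-3-phosphate synthase (chromosome X, 134329 to 135930), was 9.74-fold lower, with an FPKM of 551 in WT and 56.6 in ino4. OPI3 and CHO2, the methyltransferase genes that turn phosphatidylethanolamine into phosphatidylcholine, were 5.93-fold and 3.26-fold lower, and OPI3 (chromosome X, 572308 to 572928) had 1496 in WT and 252 in ino4. SAM2, which encodes an S-adenosylmethionine synthetase, was 4.63-fold lower, and the inositol transporter gene ITR1 was 3.19-fold lower. Middle sporulation genes were mostly lower in ino4, the opposite side of WT from bas1.

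In all, 42 genes were at least 2-fold higher in ino4 than in WT and 108 were at least 2-fold lower, or 16 and 56 with a pseudocount of 5. Of 17 phospholipid synthesis genes, 6 were at least 2-fold lower, 11 lay between and 14 had a negative difference. The median was -0.61, below all 10000 random lists (percentile 0). Of 14 fatty acid synthesis genes, FAS1 (2.51-fold) and ACC1 (2.07-fold), which encode a fatty acid synthase subunit and acetyl-CoA carboxylase, were at least 2-fold lower, 12 lay between and the median was -0.25 (percentile 0). Of 30 middle sporulation genes, 4 were at least 2-fold lower, SPS1 (2.70-fold), SPS2 (2.51-fold), SSP2 (2.33-fold) and SPS4 (2.14-fold). The other 26 lay between, 29 of the 30 had a negative difference, and the median was -0.43 (percentile 0). The 14 phosphate-responsive genes had a median of -0.33 (percentile 0), with PHM6 2.16-fold lower and PHO84 at 385 in WT and 206 in ino4. They were lower in bas1 as well, but both comparisons use the same WT values. Lists on the same side of WT in both mutants, such as these genes and ribosomal proteins, are therefore not separate results. The 18 stress genes had a median of -0.15 (percentile 0.19) and no member 2-fold apart.

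Several lists had small positive medians in ino4 that lay above the central 95% of random lists. These were one-carbon and glycine metabolism (0.23, percentile 98.90), arginine and lysine synthesis (0.23, percentile 99.81), ergosterol synthesis (0.16, percentile 99.64) and ribosomal proteins (0.11, percentile 100). No ergosterol or one-carbon gene was 2-fold apart, and among 129 ribosomal protein genes only RPL22B was, at 2.89-fold lower from an FPKM of 9.11. In the arginine and lysine list, ARG4, encoding argininosuccinate lyase, was 2.09-fold lower against the direction of the list. The marker genotypes of the strains are not given in the sources used here, so a difference between the strains at ARG4 is not excluded. Of the 21 lists, 9 lay outside the central 95%, against 1.05 for lists of genes drawn at random, which is not a chance rate for these genotypes.

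Purine synthesis genes had a median of 0.14 in ino4 (percentile 96.36), and GCV1, SHM2 and ADE17 had FPKM values of 441, 68.2 and 62.1. Medians also lay within the central 95% for histidine synthesis (0.05), the guanine branch (-0.10), the unfolded protein response (0.00), break formation (0.12), axis and synapsis (-0.04), strand exchange and repair (0.10), meiotic entry regulators (-0.02), mitotic and G1 genes (0.06), haploid mating genes (-0.04), acetate use and gluconeogenesis (0.07) and marker loci (-0.05). NDT80 had an FPKM of 282 in WT and 277 in ino4. Within the mating list, the a-factor genes MFA2 and MFA1 were 2.53-fold and 1.82-fold higher, but their entries are only 117 and 111 bp long. Entries under 300 bp were 28.6% of those at least 2-fold higher in ino4, against 3.58% of those compared. Among the marker loci, LEU2, which serves as a genetic marker in many strains, was 3.00-fold higher in ino4 (48.4 in WT and 145 in ino4), and a strain difference at this locus is not excluded.

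Outside the lists, the other entries with the largest decreases in ino4 included YGL258W-A, YDR269C, FYV5, the merged entry of YPR077C and YPR078C, and YNL266W, with log2 differences of -3.08, -2.26, -2.15, -2.10 and -2.05. The largest increases were at YIR023C-A (3.51), SNR69 (2.95), YJL064W (2.86), YBR196C-A (2.56), YOR381W-A (2.51), YML054C-A (2.45), YCL058W-A (2.15), YML100W-A (2.14), YOR282W (2.04) and YKL106C-A (1.99). Of these, YDR269C, FYV5, YNL266W, YIR023C-A, YJL064W, YCL058W-A and YOR282W are listed at the same position as another entry. FYV5 and YCL058W-A share a position (chromosome III, 23523 to 23981) and had FPKM values of 13.3 and 1.84 in WT and 2.20 and 11.6 in ino4, so their opposite differences cannot be taken as separate. Increases in ino4 were concentrated at low levels. Of the 42 genes at least 2-fold higher, 18 had a mean FPKM under 5, another 18 lay between 5 and 20 and 0 had a mean of 100 or more.

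The comparison of bas1 with ino4 set the mutants side by side, apart from WT. Middle sporulation genes were higher in bas1 than in ino4 in all 30 of 30 cases, and 18 of the 30 were at least 2-fold higher. SPS1 was 5.89-fold higher, SPS2 4.64-fold, and CDC5 and SSP1 3.66-fold each, and the list's median was 1.17 (percentile 100). Phospholipid synthesis genes were higher in bas1, 6 of 17 by at least 2-fold, with INO1 at 7.68-fold, OPI3 at 4.17-fold, the choline transporter gene HNM1 at 2.96-fold and CDS1, encoding the synthase of CDP-diacylglycerol, at 2.62-fold (median 0.59, percentile 100). GCV1, SHM2 and ADE17 were 25.8-fold, 10.4-fold and 6.43-fold lower in bas1 than in ino4.

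In this comparison 171 genes were at least 2-fold higher in bas1 and 171 were at least 2-fold lower. Lists lower in bas1 were purine synthesis (-0.76, percentile 0), one-carbon and glycine metabolism (-0.32, percentile 1.95), phosphate-responsive genes (-0.41, percentile 0.02) and mitotic and G1 genes (-0.45, percentile 0.09). Fatty acid synthesis genes (0.33, percentile 99.98) and meiotic entry regulators (0.28, percentile 99.36) were higher, the latter with NDT80 1.90-fold higher in bas1. Of the 21 lists, 8 lay outside the central 95%. The a-factor genes MFA2 and MFA1, with short entries of 117 and 111 bp, were 4.24-fold and 2.45-fold lower in bas1. STE3, the a-factor receptor gene, which is listed at the same position as another entry, was 2.36-fold higher. INO4 and BAS1 were the targeted genes among the extremes, and YGL258W-A, YDR269C and the merged entry of YPR077C and YPR078C were higher in bas1 by log2 3.48, 3.14 and 2.81, while YCR047W-A had a log2 difference of -4.51.

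**Figure D3:**
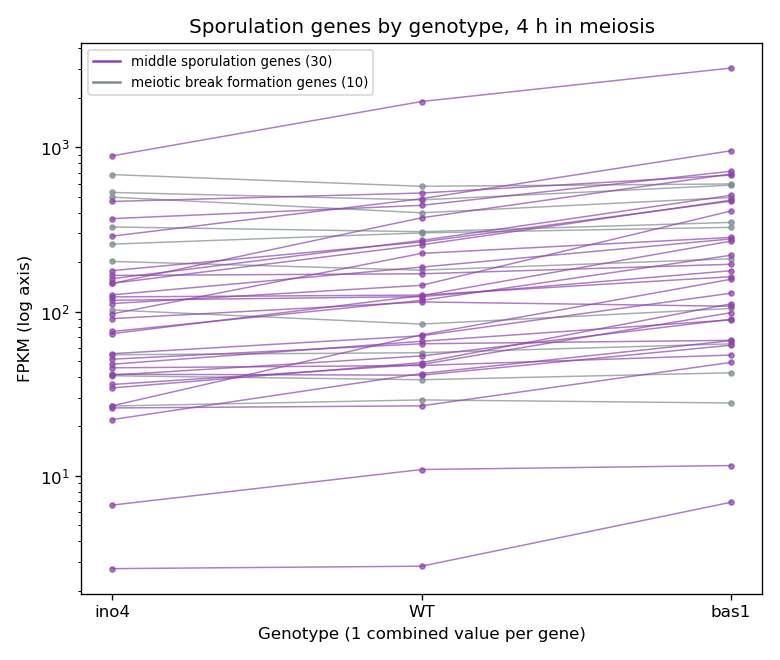
FPKM on a log axis (vertical) for the 30 middle sporulation genes (purple) and 10 break formation genes (grey) in ino4, WT and bas1 (horizontal). Each line joins the combined values of a gene. Middle genes climb from ino4 through WT to bas1 in 28 of 30 cases, while break formation genes stay near level, with medians against WT of 0.18 in bas1 and 0.12 in ino4.

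The overlap of the mutants' differences from WT asked whether the same genes were apart in both. Of the genes at least 2-fold apart from WT, 10 were higher in both mutants and 16 were lower in both, or 1 and 4 with a pseudocount of 5, and 17 were higher in both with a pseudocount of 0.1. The 10 genes higher in both were low in WT, with FPKM values from 0.262 to 14.9, and 5 of them are listed at the position of another entry. The stress-related transcription factor gene CIN5 had the highest level of the genes lower in both, with an FPKM of 850.4 in WT, 342 in bas1 and 396 in ino4. The 4 genes higher in bas1 and lower in ino4 were SPS1, PFS1, GAS2 and SPO19, all of sporulation, with SPO19 at 551 in WT, 1170 in bas1 and 253 in ino4. YCR047W-A and YBR209W were the 2 genes lower in bas1 and higher in ino4. All genes of this paragraph were named after their values were seen, except SPS1 and YCR047W-A. Independent lists would share 0.410, 2.53, 1.05 and 0.983 genes in these 4 classes. Both comparisons use the same WT values, which raises the overlap with no effect at all, and WT cannot be split because it has 1 combined column. Unchanged groups simulated against a shared WT gave 4 genes higher and 6 lower in both. Their noise was normal, scaled in each expression bin to the median absolute difference of ino4 from WT. The correlation of the differences across genes was 0.170 against 0.487 simulated, and the covariance was 0.0264 against 0.0343 simulated. The spread taken as noise holds real effects too, but it leaves out the widest differences. The simulated values are therefore not an upper limit.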

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

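The tests on middle sporulation genes and the rank of the entries listed at 0 were chosen after the results were seen, while the test of shared sequence was chosen before its outcome was known. Of the 30 middle sporulation genes, 28 were higher in bas1 and lower in ino4 than in WT, and that difference was not tested because each genotype has a single combined value. A changed share of cells in meiosis as the whole cause is argued against by 42 early genes (break formation, axis and strand exchange), with medians of 0.16 in bas1 (SD across genes 0.24, middle median 0.71) and 0.056 in ino4 (SD 0.15, middle median -0.43). Of these early genes 35 were higher in bas1, so a larger share of cells in meiosis as part of the cause in bas1 stays open, and 24 were higher in ino4. Scaling of the columns would move genes of the same level alike, and it is argued against because random lists matched on expression had a median of 0.021 in bas1 and 0.0098 in ino4. Cultures at different points of the programme at 4 h, apart from the genotype, and a genotype effect on the middle genes cannot be told apart without values per sample, and the correlation of bas1 over WT with WT over ino4 across middle genes (r 0.27) lay within the central 95% of random lists holding the same WT values (-0.62 to 0.39, median -0.13).

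Of the entries left out of every comparison, 4 were abundant in a genotype and listed at 0 in another. SED1, a major cell wall protein gene, was listed at 0 in WT and ino4 and at an FPKM of 17387 in bas1, while the merged entry of YDR133C and YDR134C had 56536 in WT, 51302 in ino4 and was listed at 0 in bas1. Reads shared between SED1 and the YDR134C region are argued against, since they had 0 words of 30 bases in common. Whether estimates were set to 0 for the entries with the most reads stays open, since each held rank 1 by FPKM times length where it was above 0 but the reads behind a value of 0 are unknown. No biological explanation was tested. YOR302W, the upstream open reading frame of CPA1, had an FPKM of 2537 in ino4 and 1405 in WT and was listed at 0 in bas1. SNR41 had 187 in ino4 and 126 in WT and was listed at 0 in bas1. By FPKM times length in WT these ranked 2224 and 5601, so they were not among the entries with the most reads there.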

How the results depend on the processing

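The 1.5-fold rule and the restrictions to entries of at least 300 bp or without overlap, and trimmed-mean and quantile scaling for the lists, were chosen after the results were seen. No paired analysis was possible because the table has 1 combined value per genotype, although the labels share replicate numbers. Settings listed beforehand but not run for the same reason were the empirical Bayes settings, fits of 4 samples, the replicate block, leaving out samples, adjusted p of 0.05 with 2-fold or of 0.10, and the camera and fry settings. Of the counts under other settings, 59 stayed within 1.5 times the reported count and 19 did not, and the cause was not tested unless the setting itself gives it. Leaving out the filter gave 8 of the 59. It could not change a 2-fold count, because each added entry has every FPKM under 1. Median and trimmed-mean scaling gave 8 each and shift all genes by a small constant, so they could hardly change a count. The 1.5-fold rule, looser by construction, gave 245 higher and 451 lower in bas1, 143 and 284 in ino4, and 418 and 506 between the mutants. A pseudocount of 5, which shrinks low genes, left 33 higher and 91 lower in bas1, 16 and 56 in ino4, and 1 higher and 4 lower in both mutants. A pseudocount of 0.1 gave 17 higher in both. A filter of FPKM 10, with fewer genes compared, gave 24 higher in ino4 and 5 higher in both. Entries of at least 300 bp gave 6 higher and 9 lower in both. Leaving out overlapping entries gave 22 higher in ino4 and 5 higher in both. Median and trimmed-mean scaling move all genes of a comparison alike and cannot test a list. Under the other settings run for lists, each list outside the central 95% of random lists kept its sign and stayed outside in 96 of 96 values. Of the lists inside, 152 values stayed inside and 4 did not, all in bas1 against WT. These were haploid mating with entries of at least 300 bp (0.19, percentile 99.21) and under quantile normalization (0.22, percentile 98.64), meiotic entry regulators under quantile normalization (0.34, percentile 99.62) and phospholipid synthesis without overlapping entries (-0.18, percentile 2.14). Of the values of named genes, 1910 moved by less than 1.5-fold and 35 by more, all under pseudocounts of 0.1 or 5, and none at least 2-fold apart changed sign. Most of the 1910 could not move, since filters leave a value unchanged and median and trimmed-mean scaling shift all genes by a small constant. With a pseudocount of 0.1, 266 values stayed and 13 moved, and with 5, 257 stayed and 22 moved. All 279 stayed under quantile normalization. Named genes under FPKM 10 have no value with that filter. The median over all genes was 0.0314 in bas1 and 0.0145 in ino4 under quantile normalization. The depth is unknown, so counting error is not known for any gene.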

Other observations

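The lists in this part (glycolysis, cell wall proteins, histones and small RNAs) and the genes named were chosen after the data were seen, as was the test of scaling, while the other tests on glycolytic genes were chosen before their outcomes were known. Glycolytic genes were lower in bas1 as a group. Of 17 genes, 15 could be compared, since HXK1 and GLK1 are merged with a neighbour, and 15 of 15 were lower, 11 by at least 2-fold, with a median log2 difference of -1.71. FBA1, encoding aldolase, had an FPKM of 2018 in WT, 657 in bas1 and 2281 in ino4. PGK1, encoding phosphoglycerate kinase, had 944, 326 and 875, and CDC19, encoding the main pyruvate kinase, had 842, 237 and 869. PYK2, the minor pyruvate kinase gene, had 37.3, 35.9 and 34.5. HXK2, PFK1 and PFK2 were also lower by less than 2-fold in bas1, with log2 differences of -0.39, -0.49 and -0.79. In ino4 the list's median was -0.09 (percentile 7.64). The list for acetate use and gluconeogenesis, which holds none of these glycolytic genes, had a median of 0.01 in bas1. In that list PCK1, of the committed gluconeogenic step, had 1859 in WT and 2903 in bas1. PCK1 lies near BAS1, beyond UBP11, and whether its difference is tied to that locus was not tested.

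Of 22 cell wall protein genes 20 could be compared, and 14 were lower in bas1, 7 by at least 2-fold, and 6 were higher (TIR1, at least 2-fold, and TIR2, TIR3, TIR4, DAN1 and DAN4), with a median of -0.61 (percentile 0); under quantile normalization 5 were 2-fold lower. CWP2 had an FPKM of 6591 in WT and 2070.4 in bas1, and CCW12 had 13366 and 5329. All 8 core histone genes were lower in bas1, 0 of 8 by 2-fold, with a median of -0.48 (percentile 0.64), and HHF2 had 11647 in WT and 8074 in bas1. Among lists matched on length too, the histone median was at percentile 3.18, within the central 95%. Of 78 small RNA genes with names beginning SNR, 35 could be compared, with a median of -0.38 in bas1 (percentile 1.51 with length matched). Of these, 8 were at least 2-fold lower, or 4 under quantile normalization, and 1, SNR69, at least 2-fold higher. Length was matched in only 5 bins, so the shortest entries were set against longer ones too. The small RNA list is therefore not shown to stand apart from its entry length. Entries under 300 bp had a median of -0.31 in bas1 and -0.02 in ino4, so the length of an entry goes with the difference in bas1. They were 3.58% of entries compared. Among entries at least 2-fold apart they were 11.7% of the higher and 20.8% of the lower in bas1. In ino4 they were 28.6% of the higher and 16.7% of the lower.

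For the glycolytic genes, the tables argue against entry length, since the list lay at percentile 0 among random lists matched on length and expression. Reads shared between paralogs are argued against too, because the 10 members with no 30-base word elsewhere in the genome had a median of -1.50. Scaling of the columns is argued against because random lists matched on expression had a median of 0.0053, and quantile normalization, which took the histone median from -0.48 to -0.33, left the glycolytic median at -1.70. An effect of Bas1 loss on these transcripts and a difference between cultures apart from the genotype were not tested and stay open, since no values per sample were used.

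LEU2 and ARG4 stood out from their neighbours in ino4. LEU2 was 3.00-fold of WT, while YCL021W-A and NFS1 to either side were 0.922-fold and 1.16-fold. In bas1 LEU2 was 1.68-fold of WT, with YCL021W-A at 1.65-fold and NFS1 at 0.963-fold. ARG4 in ino4 was 0.478-fold of WT, while YSC83 and DED81 on either side were 0.966-fold and 1.23-fold. The marker genotypes of the strains are not given in the sources used here, so a difference between the strains at these loci was not excluded. The medians of the 16 nuclear chromosomes ranged from -0.04 to 0.05 in bas1 and from -0.04 to 0.09 in ino4.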
